A study of Mus musculus with 24 samples.

How the data were processed

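Total RNA from testis, spleen and brain of mice was copied into biotin-labelled cRNA and hybridised to Illumina MouseRef-8 bead arrays, with 1 animal per array and 24 arrays in all, per the labels' protocols. RNA had been extracted with Trizol and cleaned on columns, and its quality was examined by gel electrophoresis. The values used here are intensity values that the authors deposited in a single table for the whole series, on a linear scale with the background already subtracted, beside a detection p-value for each probe and array, per the file headers. GenomeStudio 2011.1 is the tool named in the submitters' processing notes. Between 22.2% and 25.1% of the intensities of an array lay below 0, which plain subtraction of a background produces and which have no logarithm. A normalized table of the same arrays had also been deposited. Its values were linear and had nearly the same median on every array, between 24.0 and 24.2, so it had been scaled over all 24 arrays together, by a method not given in the sources used here. That table served only as an alternative, because its normalization was unknown. No slide or scan date was given, so neither could be tested as a batch.

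From the deposited intensities, background correction and quantile normalization were done with the neqc function of limma 3.58.1 in R 4.3.3, separately for the 8 arrays of each tissue, with the negative-control distribution inferred from the detection p-values. A probe entered the tests of a tissue when its detection p was under 0.05 on at least 4 of the 8 arrays. This left 13152 probes in testis, 12449 in spleen and 14027 in brain, for 9271, 8861 and 9745 genes. Values near the floor are compressed by this correction, so fold changes of dim probes understate the true ones. Of the 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 had none. Updating the symbols through the gene identifiers changed 0 of them, and 23962 probes were placed on a chromosome from the reference gene table of assembly GRCm38.p6, which was used for names and gene neighbourhoods only. Probes without a symbol were counted and not named. Every column of the tables used was mapped to a sample.

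Mutants and controls were compared within each tissue by a linear model per probe with empirical Bayes moderation (lmFit and eBayes of limma), and adjusted p-values are Benjamini-Hochberg values over the probes of that tissue. A probe counted as past the threshold when its adjusted p was under 0.05. Differences are given on the log2 scale as mutant minus control, means with their SD over 4 animals, and differences with the moderated standard error (SE). The animals of a group are separate mice, so the p-values measure the spread between animals. In testis and spleen the controls comprised 2 wild-type and 2 heterozygous mice by their identifiers, pooled as the labels pool them. A further model with 3 genotypes compared heterozygous with wild-type controls in these tissues. Whether an effect differed between tissues was tested by an interaction contrast over the arrays of all 6 groups, each tissue normalized on its own and the animal entering as a random block through duplicateCorrelation. The estimated correlations were 0.0170, 0.0136 and 0.0150, and were reused in the fits that left out an array or regrouped the animals. Probes past the threshold in a pair of tissues were compared with Fisher's exact test.

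Gene lists were 42 sets of textbook markers: the SMC5/6 complex and its chromosome neighbours, other chromosome and DNA repair factors, cell cycle, stress and interferon responses, the cell types of testis, spleen and brain, and tissues that could be carried over in dissection. A list was tested in a tissue when at least 5 of its genes were measured, each by its detected probe with the highest mean, which left 32 lists in testis, 31 in spleen and 32 in brain. The list of replication-dependent histones had been written in former symbols, matched 0 genes and was not tested, although the array has such probes. The set test was camera of limma with a preset correlation between genes of 0.01, adjusted over the lists of a tissue, which asks whether a list shifts relative to the other genes. Camera with an estimated correlation and fry were run beside it. The comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. That rule names every Smc6 probe, the probes past the threshold, the 5 higher and 5 lower probes of a tissue with the smallest p, up to 4 members of each described list that passed or otherwise the 2 with the smallest p, and up to 5 probes past the threshold per interaction or heterozygote contrast. Genes outside the rule are said to have been chosen after their values were seen.

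The method was tested on simulated data built on the means and spreads of the real probes, with 200 probes changed in each comparison. In testis it recovered 16% of probes changed 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 3-fold among 13152 probes. In spleen the shares were 6%, 34%, 84% and 100% among 12449 probes, and in brain 20%, 90%, 98% and 100% among 14027. False calls made up 5.06%, 6.67% and 2.53% of all calls in the respective tissues. The interaction tests were simulated on the arrays of each pair of tissues alone, without an animal block. There a 2-fold difference was recovered for 86% of probes between testis and spleen, 100% between testis and brain and 90% between spleen and brain. A shift of 0.3 planted in 1 list was found in each tissue also with an estimated correlation, with 0 other lists called. The simulated noise was drawn independently for each probe and array. Correlation between genes and structure of the samples were therefore absent, and the shares of false calls hold only under that condition. The recovered shares hold for 200 changed probes, since the adjusted threshold grows stricter when fewer change. In the real testes Rgs6 differed 1.51-fold and did not pass (limma adjusted p = 0.395). The number of arrays limits the precision: the median SE of a difference was 0.11 in testis, 0.15 in spleen and 0.09 in brain.

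The alternatives comprised other background corrections and normalizations, the deposited normalized table, other filters on dim probes, other variance models, a joint model of the 3 tissues, the replicate number as a block, other thresholds, wild-type or heterozygous controls alone, and each array left out in turn. Offsets of 16 or 50 were added before the logarithm in some of them. Further alternatives were chosen after seeing the data: the spleen comparison without both arrays that carried pancreas transcripts, and covariates for the erythroid, spermatid, pancreas or Gh level or the brightness of an array. The counts of other splits of the samples, the chromosome tests, the brightness test and the test of a list of glucocorticoid-induced genes, written for the purpose, were likewise chosen after results had been seen. No human data were involved, and no sample was left out of the comparisons.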

Results

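SMC6 is a subunit of the SMC5/6 complex, a relative of cohesin and condensin that acts in DNA repair by homologous recombination. Transcripts were measured in testis, spleen and brain of male mice homozygous for a mutation in Smc6 and of control mice, to ask how each tissue's transcriptome differed between them. The mice were of a mixed background of C57BL/6J, 129ola and FVB. Each tissue had 4 mutants and 4 controls, 1 animal per array. Testis and spleen came from the same 8 animals at 12 weeks of age, and brain came from other animals at 19 weeks. In testis and spleen the mouse identifiers mark control replicates 1 and 2 as wild type and 3 and 4 as heterozygous, although the genotype label calls all 4 wildtype, and the brain controls were all wild type. Between 12708 and 13344 of the 25697 probes were detected per testis array, 12049 to 13134 per spleen array and 13784 to 14234 per brain array.

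The Smc6 transcript itself did not differ between mutants and controls in any tissue by more than the spread between animals. Its probe, ILMN_2728385, read 8.14 ± 0.15 in control and 8.11 ± 0.12 in mutant testes (log2 intensity, mean ± SD, n = 4 each), a difference of -0.04 (SE 0.10, limma adjusted p = 1.00). In spleen it read 6.23 ± 0.21 in controls and 6.42 ± 0.26 in mutants, a difference of 0.19 (SE 0.16, limma adjusted p = 1.00). In brain the levels were 6.34 ± 0.06 and 6.31 ± 0.15, a difference of -0.03 (SE 0.09, limma adjusted p = 0.931). The labels do not say what the mutation does to the transcript, so its level does not check the genotypes.

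**Figure D1:**
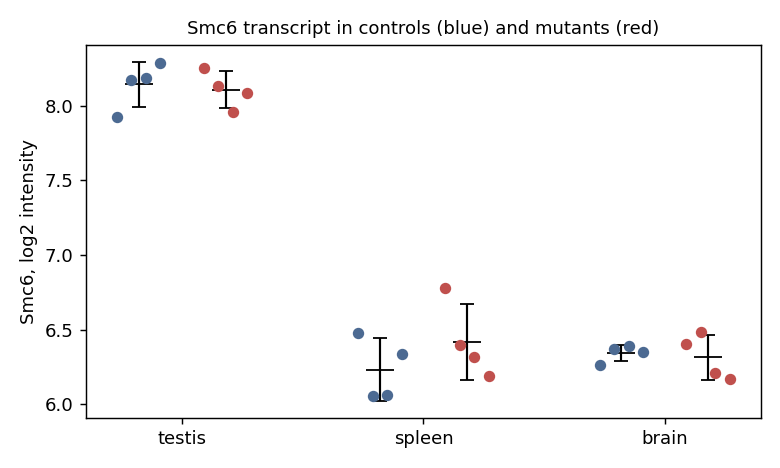
Log2 intensity of the Smc6 probe (vertical axis) in each tissue (horizontal axis), with a point per animal, controls in blue and mutants in red, and bars for the mean ± SD of 4 animals. Control and mutant values overlap in every tissue, around 8.14 and 8.11 in testis and 6.34 and 6.31 in brain.

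In testis no single transcript passed the test between Smc6 mutants and controls, and the lists of germ cell stages had medians near 0. Spermatid genes, 33 of which were measured, had a median difference of -0.02, with Catsper1, part of the sperm calcium channel, at -0.25 (SE 0.10) and Tssk2, a sperm kinase, at -0.19 (SE 0.08). The 25 genes of meiotic spermatocytes had a median of 0.02, with Msh4, needed for meiotic crossovers, at 0.31 (SE 0.09) and Psmc3ip at -0.22 (SE 0.08). The 10 measured genes of the spermatogonia list had a median of -0.07, with the germline transcription factor Sohlh2 at 0.35 (SE 0.10) and Prdm9, which places meiotic recombination hotspots, at 0.22 (SE 0.12). Over all genes 0 of these members passed, and adjusted over the list alone 1 did, Sohlh2. The 3 lists had camera adjusted p = 0.462, 0.969 and 0.969.

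The somatic and repair genes of the testis did not pass either. The 19 measured genes of homologous recombination had a median difference of 0.03 and a mean of -0.01 (camera adjusted p = 0.969, direction down). Among them Xrcc3 read -0.32 (SE 0.12) and Helq 0.17 (SE 0.09). The 5 measured genes of the SMC5/6 complex had a median difference of 0.02 (camera adjusted p = 0.969), with the subunits Nsmce1 at 0.12 (SE 0.08) and Eid3 at -0.09 (SE 0.10). The 22 targets of p53, the transcription factor that answers DNA damage, had a median of 0.01 (camera adjusted p = 0.941), with Plk2 at 0.23 (SE 0.12) and Ercc5 at 0.20 (SE 0.11). Sertoli cell genes had a median of -0.04 over 18 genes (camera adjusted p = 0.845), with the inhibin subunit gene Inhbb at -0.25 (SE 0.10) and Rhox5 at 0.13 (SE 0.08). Leydig cell genes had a median of -0.01 over 9 genes (camera adjusted p = 0.845), with Ptgds at -0.20 (SE 0.14) and the peptide hormone gene Insl3 at -0.15 (SE 0.11). In all of these lists 0 members passed, over all genes or adjusted over the list alone.

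The 2 testis lists that passed camera were of tissues outside the seminiferous tubule, and both were higher in mutants. Of 14 pancreas genes, 13 lay above 0 with a median of 0.54 (camera adjusted p = 0.00273, and adjusted p = 0.991 with an estimated correlation), with the lipase relative Pnliprp1 at 1.05 (SE 0.57) and the ribonuclease gene Rnase1 at 0.93 (SE 0.58). The pancreas genes were high in 1 testis, mutant replicate 1, where their median was 7.62 against 4.72 to 5.64 in the other 7, and without that animal the list's median difference was 0.02. Of 6 genes from the choroid plexus list, 5 lay above 0 with a median of 0.19 (camera adjusted p = 0.0248, and adjusted p = 0.620 with an estimated correlation), with Calml4, a calmodulin-like gene, at 0.39 (SE 0.16) and Folr1, a folate receptor, at 0.19 (SE 0.10). The median of this list was 0.0339 with no filter on dim probes and 0.12 to 0.24 without single arrays. In both lists 0 members passed, over all genes or adjusted over the list alone. Without control replicate 4 or mutant replicate 1, 0 lists passed in testis, and without control replicate 2, control replicate 3 or mutant replicate 3, 1 did. The other 30 lists had camera adjusted p between 0.202 and 0.993.

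Over the 13152 testis probes limma called 0, with 629 at an unadjusted p under 0.05 where 658 would be found by chance. The probes with the smallest p were higher in mutants for Rgs6, a regulator of G-protein signalling (0.60, SE 0.09, limma adjusted p = 0.395), Susd3 (0.50), Hp, which encodes haptoglobin (0.61), Bclaf3 (0.58) and Retreg1 (0.46). They were lower for Ppp1r32 (-0.45), Sidt2 (-0.41), Nsmce2, the SUMO ligase of the SMC5/6 complex (-0.59, SE 0.13, while its brighter probes read -0.17 and 0.05), Gdpd5 (-0.41) and Tbrg1 (-0.50), and these 9 had limma adjusted p = 0.831. The groups did not overlap for 2.71% of probes, against 2.86% by chance. The confidence interval of the difference lay within 2-fold for 99.7% of probes and within 1.5-fold for 96.8%.

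In spleen no single transcript passed the test, and the list that did was of pancreatic acinar genes. All 9 measured pancreas genes were higher in mutants, with a median difference of 2.34 (camera adjusted p = 3.3e-15, and adjusted p = 0.831 with an estimated correlation). The elastase Cela2a read 5.72 ± 0.28 in controls and 9.09 ± 3.49 in mutants (3.37, SE 1.28, limma adjusted p = 1.00), and Pnliprp1 read 4.61 ± 0.15 and 7.58 ± 2.90 (2.97, SE 1.06). Over all genes 0 of the 9 passed, and adjusted over the list alone 8 did. The wide spread came from 2 animals: the list's median was 10.48 in mutant replicate 1 and 9.54 in mutant replicate 2, 5.00 and 5.36 in mutant replicates 3 and 4, and 4.55 to 5.20 in the controls. In the spleen comparison without those 2 arrays, chosen after seeing the data, the list's median was 0.16.

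**Figure D2:**
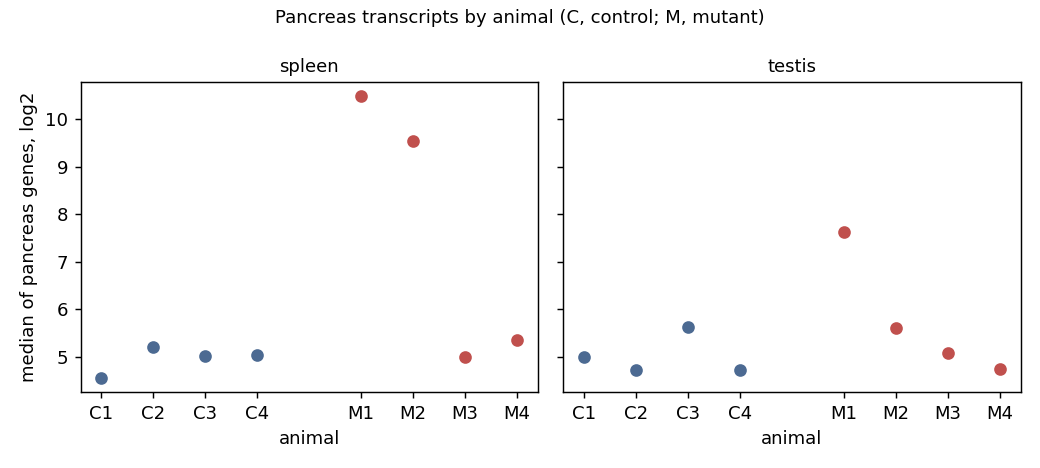
Median log2 intensity of the pancreas genes (vertical axis) in each animal's spleen (left) and testis (right), C for controls in blue and M for mutants in red, with a point per animal. In spleen mutants 1 and 2 stand at 10.48 and 9.54 and the other 6 animals between 4.55 and 5.36, and in testis mutant 1 stands at 7.62.

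The blood cell lists of the spleen did not pass. B cell genes had a median difference of 0.07 over 15 genes (camera adjusted p = 0.368), with Fcrl1 at 0.44 (SE 0.27) and the kinase Blk at 0.20 (SE 0.16). T cell genes had a median of -0.03 over 20 genes (camera adjusted p = 0.883), with Cd4 at -0.33 (SE 0.26) and the transcription factor Bcl11b at -0.16 (SE 0.23), which turned to 0.16 and 0.06 without the 2 arrays that carried pancreas transcripts. Of 19 erythroid genes, 17 lay above 0 with a median of 0.18 (camera adjusted p = 0.231), with Hemgn at 0.35 (SE 0.50) and ferrochelatase, Fech, at 0.32 (SE 0.47). The median of the erythroid genes ranged from 6.84 to 9.07 between single spleens. Granulocyte genes had a median of 0.03 over 20 genes (camera adjusted p = 0.723), with Stfa1 at 0.15 (SE 0.15) and the receptor Csf3r at -0.14 (SE 0.32). In these 4 lists 0 members passed, over all genes or adjusted over the list alone.

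Genes of the damage, interferon and division programmes did not pass in spleen. The 25 p53 targets had a median of -0.06 (camera adjusted p = 0.686), with Sesn1 at -0.45 (SE 0.14) and the cell cycle inhibitor Cdkn1a at 0.34 (SE 0.17). The 29 interferon-stimulated genes had a median of 0.06 (camera adjusted p = 0.368), with Ifi205 at 0.18 (SE 0.14) and Rtp4 at -0.16 (SE 0.13). The 19 mitotic genes had a median of -0.01 (camera adjusted p = 0.883), with the checkpoint kinase gene Bub1b at -0.29 (SE 0.20) and cyclin A2, Ccna2, at -0.15 (SE 0.19). In these 3 lists 0 members passed, over all genes or adjusted over the list alone. The 30 lists that did not pass had camera adjusted p between 0.231 and 0.984, but the number that passed was 10 without mutant replicate 2, 6 without control replicate 4, 4 without control replicate 1 and 2 without control replicate 2 or 3.

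Over the 12449 spleen probes limma called 0, with 216 at an unadjusted p under 0.05 where 622 would be found by chance. Smallest in p among the higher probes were Tyrobp, an adaptor of myeloid receptors (0.39, SE 0.12), Ccdc28a (0.46), Erdr1 (1.04, SE 0.35), Las1l (0.36) and Sars, a seryl-tRNA synthetase (0.36). Among the lower ones were Bclaf3 (-0.53, SE 0.12), Tagap (-0.66), Elp2 (-0.47), Map1lc3b, a marker of autophagosomes (-0.55), and Arhgap18 (-0.58), and all 10 had limma adjusted p = 1.00. The groups did not overlap for 1.33% of probes, against 2.86% by chance. The interval of the difference lay within 2-fold for 98.6% of probes and within 1.5-fold for 82.5%.

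In brain 4 probes rose in Smc6 mutants and 0 fell. They read the genes Etv1, an ETS family transcription factor, Mbp, the basic protein of myelin, Sh3gl2, an endophilin of synaptic vesicle endocytosis, and Tsc22d3, a leucine zipper protein induced by glucocorticoids. Etv1 (ILMN_2643915) rose from 6.30 ± 0.13 to 7.07 ± 0.14 (n = 4 each), by 0.77 (SE 0.09) or 1.70-fold, and Tsc22d3 (ILMN_2701664) from 6.63 ± 0.15 to 7.57 ± 0.26, by 0.95 (SE 0.13) or 1.93-fold. Sh3gl2 (ILMN_2701695) rose from 7.89 ± 0.05 to 8.50 ± 0.13, by 0.61 (SE 0.08) or 1.53-fold, and Mbp (ILMN_3081854) from 10.10 ± 0.08 to 10.65 ± 0.06, by 0.55 (SE 0.07) or 1.47-fold. Each had limma adjusted p = 0.0442 and was higher in all 4 mutants than in all 4 controls.

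**Figure D3:**
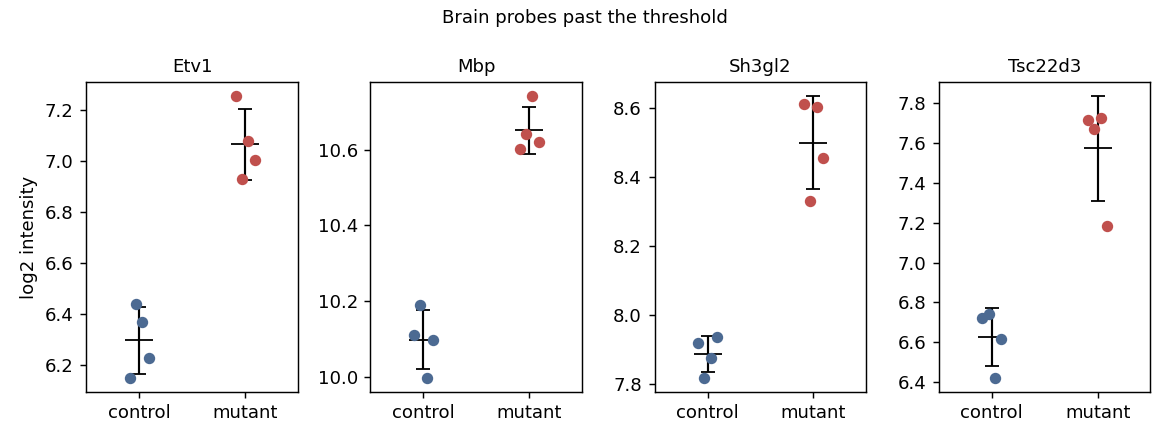
Log2 intensity of the 4 brain probes past the threshold (vertical axes, not starting at 0) in controls (blue) and mutants (red), with a point per animal and bars for the mean ± SD of 4 animals. For each probe all mutants lie above all controls, with Etv1 at 6.30 ± 0.13 and 7.07 ± 0.14 and Tsc22d3 at 6.63 ± 0.15 and 7.57 ± 0.26.

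Other probes of the same 4 genes read a similar difference for Etv1 and for 1 of the Sh3gl2 probes, and a smaller or opposite one otherwise. The second Etv1 probe read 0.68 (SE 0.11) and a second Sh3gl2 probe 0.60 (SE 0.09), each with limma adjusted p = 0.0668. The brightest Sh3gl2 probe, at 13.11 ± 0.03 in mutants, differed by 0.01 (limma adjusted p = 0.977). The other Mbp probes read -0.19 (limma adjusted p = 0.306) and 0.01 (limma adjusted p = 0.965), and the brighter Tsc22d3 probe 0.26 (limma adjusted p = 0.280). Without control replicate 3, control replicate 4, mutant replicate 1 or mutant replicate 3 the brain count in limma was 0, with 1435, 1672, 1362 and 1503 probes at an unadjusted p under 0.05, and without mutant replicate 4 it was 1. It was 3 without control replicate 1, control replicate 2 or mutant replicate 2, with 0, 1 and 2 of the 4 among them. Over these 8 fits Etv1 passed in 2, Sh3gl2 and Tsc22d3 in 1 each and Mbp in none. The deposited normalized values called 1 probe, and none of the 4 was shared.

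Beyond these 4, more brain probes had a small p than the number expected by chance. Other splits of the same 8 arrays gave up to 1550 at an unadjusted p under 0.05, so chance is not firmly excluded. At an unadjusted p under 0.05 there were 1660 of 14027 where 701 would be found by chance, 894 higher and 766 lower in mutants, and the groups did not overlap for 6.66% of probes against 2.86% by chance. Next in p among the higher genes were the actin branching subunit Arpc5 (0.47), the leucine zipper gene Tsc22d1 (0.56) and the chaperone Hspa8 (0.59), each with limma adjusted p = 0.0668. The lower genes with the smallest p were Def6 (-0.54, limma adjusted p = 0.0810), Trappc12 (-1.06, SE 0.20, limma adjusted p = 0.0925), Pgm5 (-0.43), the Notch target Hes5 (-0.70, SE 0.14, limma adjusted p = 0.104) and the ubiquitin ligase Wwp2 (-0.40, limma adjusted p = 0.109). Hes5 read -0.18 with array brightness as a covariate, chosen after seeing the data. Over the alternatives other than leaving out an array, the smallest difference was -0.23 for Def6, -0.70 for Trappc12, -0.21 for Pgm5 and -0.19 for Wwp2. In testis and spleen the same 4 animals, 2 controls and 2 mutants, were lowest for Trappc12. The mutant brain arrays were also dimmer, with an upper quartile of the signal of 152 ± 7.24 against 177 ± 8.27 in controls (exact permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.129 adjusted over 9 such tests). The interval of the difference lay within 2-fold for 99.8% of probes and within 1.5-fold for 95.6%.

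Of 32 brain lists, 3 passed camera, all upward, and none did with an estimated correlation. All 12 measured genes of the choroid plexus, the epithelium that makes cerebrospinal fluid, lay above 0 with a median of 0.21 (camera adjusted p = 8.56e-06, and adjusted p = 0.720 with an estimated correlation). Its members Kl, the klotho gene, and Sostdc1 read 0.39 (SE 0.10) and 0.34 (SE 0.10), and 0 of the 12 passed over all genes and 3 adjusted over the list alone. Of 14 heat shock genes, 11 lay above 0 with a median of 0.12 (camera adjusted p = 0.0222, and adjusted p = 0.720 with an estimated correlation), with the small chaperones Cryab at 0.25 (SE 0.08) and Hspb1 at 0.40 (SE 0.19). Its median turned to -0.0184 with array brightness as a covariate, chosen after seeing the data. Of 56 cytosolic ribosomal protein genes, 39 lay above 0 with a median of 0.04 (camera adjusted p = 0.00662, and adjusted p = 0.720 with an estimated correlation), with Rps13 at 0.27 (SE 0.07) and Rpl7a at 0.23 (SE 0.07). In the latter lists 0 members passed, over all genes or adjusted over the list alone. The heat shock list no longer passed without control replicate 1, 2 or 4 or mutant replicate 1 or 4 (camera adjusted p up to 0.108), nor the ribosomal list without mutant replicate 4 (camera adjusted p = 0.0927).

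Microglia, neurons, oligodendrocytes and astrocytes, and the hippocampus and cortex, had lists that did not pass camera. Of 17 microglia genes, 15 lay below 0 with a median of -0.09 (camera adjusted p = 0.0745), with Tyrobp at -0.37 (SE 0.10) and Cd14 at -0.30 (SE 0.10). Genes of hippocampus and cortex had a median of -0.13 over 9 genes (camera adjusted p = 0.0745), with Fibcd1 at -0.24 (SE 0.08) and Wfs1 at -0.20 (SE 0.09). Neuronal genes had a median of -0.02 over 20 genes (camera adjusted p = 0.645), with the kinase Camk2a at -0.26 (SE 0.08) and the glutamate transporter Slc17a7 at -0.36 (SE 0.11). Oligodendrocyte genes had a median of 0.02 over 16 genes (camera adjusted p = 0.259), with Cspg4 at 0.29 (SE 0.08) and the myelin protein Mog at 0.26 (SE 0.09). Among 13 astrocyte genes the median was -0.02 while the mean was 0.04 (camera adjusted p = 0.566), with the filament protein Gfap at 0.37 (SE 0.09) and Fgfr3 at 0.22 (SE 0.14). With each gene read by its brightest probe, which for Mbp differed by 0.01, 0 members of these lists passed over all genes, and adjusted over the list alone only Gfap did.

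The p53 targets and interferon-stimulated genes of the brain did not shift as lists. Among 24 p53 targets the median was -0.01 while the mean was 0.03 (camera adjusted p = 0.611). Cdkn1a read 8.33 ± 0.14 in controls and 8.82 ± 0.10 in mutants, a difference of 0.49 (SE 0.09, limma adjusted p = 0.0769), and passed adjusted over the list alone, while the adenylate kinase gene Ak1 read -0.25 (SE 0.08). The 20 interferon-stimulated genes had a median of 0.00 and a mean of -0.01, where camera gave the direction as up (adjusted p = 0.786), with Irf9 at 0.34 (SE 0.10) and Rsad2 at 0.24 (SE 0.11). In fry, which asks whether a list moves one way on balance without comparing it with other genes, the list of hippocampus and cortex (lower) and the Sertoli list (higher) passed in brain, each with adjusted p = 0.0228, and 0 lists did in testis and spleen. Tested for change in either direction, 6 lists passed in brain, 1 in testis and 0 in spleen. The brain lists were those of p53 targets (adjusted p = 0.00122), erythroid cells (0.00628), oligodendrocytes (0.0126), hippocampus and cortex (0.0258), ribosomal proteins (0.0258) and the Smc6 neighbours on chromosome 12 (0.0316), and the testis list was that of adipose tissue (0.0451). The other 29 lists had camera adjusted p between 0.0745 and 0.977.

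Between tissues the mutant difference passed limma's interaction test for 2 genes, and splits of the animals, given below, do not exclude chance for either. Bclaf3 read 0.58 in testis and -0.53 in spleen, a difference of 1.11 (SE 0.16, limma adjusted p = 0.00342), the only probe past the threshold of 10313 tested in both. Its testis values were 4.47 to 4.89 in controls and 5.04 to 5.38 in mutants, and it was detected in 1 of the 4 control testes. Rgs6 read 0.60 in testis and -0.14 in brain, a difference of 0.74 (SE 0.12, limma adjusted p = 0.0304), the only one of 10630, and leaving out single arrays moved its adjusted p between 0.0171 and 0.124. In control testes Rgs6 averaged 4.82 ± 0.14 and was detected in 3 of the 4. Brain came from other animals at 19 weeks with wild-type controls only, so in contrasts with brain the tissue cannot be told apart from age and control genotype. Between spleen and brain limma called 0 of 10729 probes, with 409 at an unadjusted p under 0.05 where 536 would be found by chance, and Tyrobp came closest (0.76, SE 0.13, limma adjusted p = 0.0693). Rgs6 did not pass without control replicate 1, 3 or 4 or mutant replicate 1, 3 or 4 of testis, nor without control replicate 1 or 3 or mutant replicate 1, 2 or 4 of brain.

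No gene passed in a pair of tissues. At an unadjusted p under 0.01, 1 probe was shared, lower in testis and brain, where 0.524 would be found by chance (Fisher's exact test, p = 0.410). Across probes, which are not independent replicates, the differences correlated with r = 0.08 between testis and spleen (Spearman -0.01), -0.01 between testis and brain (Spearman -0.01) and 0.15 between spleen and brain (Spearman 0.14).

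Among the controls, Cfap69, a gene of the sperm flagellum, was far lower in heterozygous than in wild-type testes. Its probe ILMN_2714209 averaged 11.66 in the 2 wild types, 6.77 in the 2 heterozygotes and 10.99 ± 0.28 in the 4 mutants, and heterozygotes lay lower than wild types by 4.90 (limma, log2 difference -4.90, SE 0.23, adjusted p = 3.23e-06). The second probe, ILMN_2628236, averaged 9.73, 6.77 and 9.18, a difference of -2.96 (SE 0.25, limma adjusted p = 0.000822), and did not pass in the deposited normalized values. Apoh, the gene of apolipoprotein H, averaged 6.48 in wild types, 5.46 in heterozygotes and 5.64 in mutants, a difference of -1.02 (SE 0.13, limma adjusted p = 0.0336), and did not pass under the 3 alternatives run for it (adjusted p from 0.0639 to 0.316). These 3 probes were the only ones past the threshold, all lower, with 784 at an unadjusted p under 0.05 where 658 would be found by chance. In spleen limma called 0 probes between these genotypes, with 274 at an unadjusted p under 0.05 where 622 would be found by chance. Each side of this comparison held 2 animals.

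**Figure D4:**
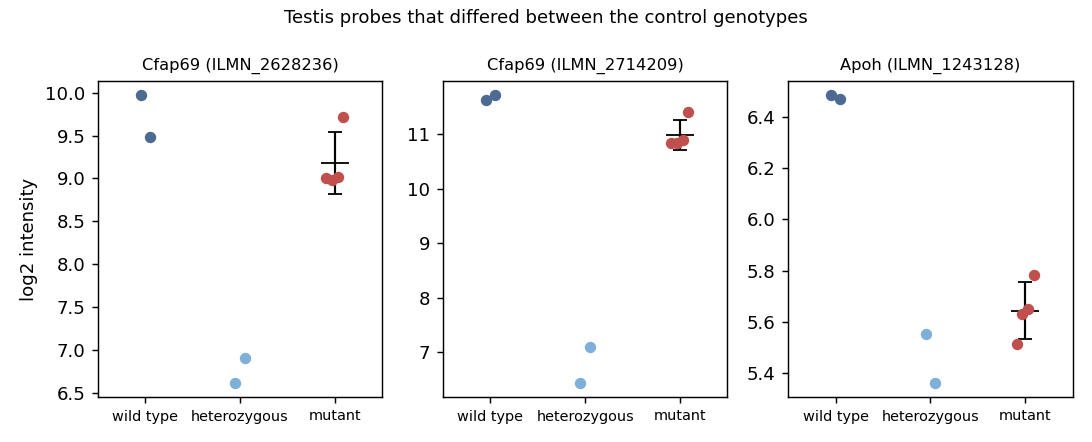
Log2 intensity of both Cfap69 probes and the Apoh probe in testis (vertical axes, not starting at 0) for wild-type and heterozygous controls and homozygous mutants, with a point per animal and bars for the mean ± SD of the 4 mutants. For Cfap69 both heterozygotes lie below all other animals, with means of 6.77 against 11.66 in wild types for ILMN_2714209.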

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

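The counts of other splits of the samples and the tests on pancreas genes and on array brightness were chosen only after the results were seen.

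The effect of the mutation on Bclaf3 differed between testis and spleen by 1.11 on the log2 scale in limma's test of the difference itself. Of 35 splits of the animals, 9 gave at least the 1 probe of the real split, so chance is not excluded, and the highest other gave 604, which points to a structure of the samples. For Rgs6 the effect differed between testis and brain by 0.74. Of 100 splits drawn, 5 gave as many probes as the real 1, with 1 in the highest other, so chance is not excluded. Between spleen and brain the real count was 0, which all 100 splits reach by construction, so chance was not tested there, and the highest other gave 563.

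A sample stood far from the other 3 of its group in 15 of the 216 groups of 4 tested, 6.94%, where chance gives about 1 in 20. In testis controls these were Ptgds in replicate 2, at 8.25 against 8.45 to 8.48, and Ercc5 in replicate 3, at 7.39 against 7.79 to 7.81. In testis mutants Susd3 stood low in replicate 3, at 6.20 against 6.44 to 6.46, while Ppp1r32 and Nsmce2 stood high in replicate 4, at 7.89 against 7.60 to 7.61 and 5.60 against 5.25 to 5.30. In spleen controls Bclaf3 read 5.76 in replicate 3 against 5.60 to 5.61, and Stfa1 read 4.80 in replicate 2 against 4.36 to 4.39. In spleen mutants Tagap read 4.85 in replicate 1 against 5.19 to 5.25, and Fech read 5.66 in replicate 2 against 7.52 to 7.65. In brain controls replicate 2 was high for Arpc5, at 6.97 against 6.81 to 6.84, and for the median of the choroid plexus list, at 6.26 against 6.16 to 6.17. In brain mutants replicate 4 was low for Tsc22d3, at 7.18 against 7.67 to 7.72, and for Sostdc1, at 6.27 against 6.61 to 6.66. Def6 read 4.84 in brain mutant replicate 3 against 5.06 to 5.10, and the median signal of brain mutant replicate 1 was 16.7 against 15.4 to 15.6.

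In 9 of the 9 measured pancreas genes mutants 1 and 2 were the 2 highest spleens, and these exceeded the controls by 5.06 in the list's median but mutants 3 and 4 by only 0.228, which argues against an effect of that size in every mutant spleen. A smaller shared effect stays open, with mixed values. Pnliprp1 read 5.00 and 5.17 in mutants 3 and 4 against 4.78 in the highest control. Cela2a read 5.39 and 6.84 in the same mutants, against 5.40 to 6.07 in controls. In the list's median 3 mutants lay above the highest control, and mutant 3 did not. In testis mutant 1, from an animal whose spleen was high, the pancreas genes exceeded the other testes by a median of 2.61, but 34 B cell and erythroid genes by only 0.00329, which argues against spleen material in that testis. Pancreatic tissue in single samples, taken in dissection, may be the source, since the pancreas lies against the spleen. A process confined to some mutants stays open as well, as no sample was examined for tissue.

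In brain 1660 probes had an unadjusted p under 0.05, and 1 of the 35 splits of the 8 arrays gave as many, the real one, with 1550 in the highest other. This argues against chance for that count taken alone. It is the smallest share that 35 splits can give and was not adjusted over the other counts tested in this way, so chance is not firmly excluded. Nor is chance excluded for the 4 probes past the adjusted threshold, reached by 2 of 35 splits with 4 in the highest other, or for the 3 lists, reached by 10 of 35 with 6 in the highest other. The mutant arrays were dimmer, but the slope of each probe on brightness within groups predicted effects that correlated with the mutant effects at -0.102 across probes (one-sided exact p = 0.958 over 576 shuffles), where brightness as the whole cause would give 0.559, which argues against it. With brightness as a covariate 814 probes had an unadjusted p under 0.05 and limma called 0. For the 4 called probes both the differences and the standard errors grew: Etv1 read 0.77 (SE 0.09) before and 1.08 (SE 0.18) after, and Tsc22d3 0.95 (SE 0.13) and 1.18 (SE 0.27). Other values shrank or turned: Hes5 went from -0.70 to -0.18 and the median of the heat shock list from 0.12 to -0.0184. Every mutant array was dimmer than every control, with an upper quartile of 145 to 162 against 169 to 189. The covariate therefore overlaps with the genotype, which widens standard errors. For that reason the drop to 814 probes and 0 calls does not show that brightness was the cause. An effect of the mutation, a slide or RNA quality stay open, untested.

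The counts of 0 probes past the adjusted threshold in testis and spleen are reached by 35 of 35 splits by construction, so chance was not tested there, and the highest other splits gave 1 and 663. For the other counts chance is not excluded. In testis 26 of 35 splits gave at least the 629 at an unadjusted p under 0.05, with 814 in the highest other, and 5 of 35 gave at least 2 lists, with 3. In spleen 33 of 35 splits gave at least 216 at an unadjusted p under 0.05 and 35 of 35 at least 1 list. The highest other splits of the spleens gave 2947 at an unadjusted p under 0.05 and 14 lists. The split with 663 set controls 1 and 3 with mutants 1 and 2, and so large a count points to a structure of the samples that the genotype does not follow.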

How the results depend on the processing

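The comparison without both pancreas-bearing spleen arrays and the covariates for Gh, array brightness and the erythroid, spermatid and pancreas levels were chosen only after the results were seen. Among 101 results on genes other than Smc6, lists and contrasts, 1973 of 2121 alternative values kept their direction and their side of the threshold, 98 lost and 43 gained a call, and 7 turned sign. Most of these results had not passed and had no call to lose, so the total does not describe those that had passed. Apart from fits that left out an array, Etv1 and Sh3gl2 kept their brain call in 7 of 13 alternatives, and Mbp and Tsc22d3 in 6 of 13. Dim signal limits these data, since filters on detection decided which probes entered. A block for slide or scan was not run because neither was given.

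The testis count of 0 became 1 in the joint model of the tissues and 2 with heterozygous controls only, and the spleen count was 0 in every alternative, with 142 to 756 probes at an unadjusted p under 0.05 in limma. The brain count of 4 became 58 with a normexp offset of 50 (49 higher, 9 lower), 18 with median scaling, 32 with neqc over all 24 arrays, 16 for probes detected on all 8 arrays, 79 with a trended and robust variance (64 higher, 15 lower) and 11 with array weights, and the same 4 were among them each time. It was 50 in the joint model (33 higher, 17 lower), 2 of them shared, and 40 at an adjusted p under 0.10. It fell to 1, lower and not shared, with log2 of the intensity plus 16 and likewise in the deposited normalized values, and to 0 with no filter, with Gh and with brightness as a covariate, where limma had 2401, 1711 and 814 probes at an unadjusted p under 0.05. Leaving out single arrays gave 0 to 3: 0 without control 3, control 4, mutant 1 or mutant 3 (1435, 1672, 1362 and 1503 at an unadjusted p under 0.05), 1 without mutant 4, and 3 without control 1, control 2 or mutant 2, of which 0, 1 and 2 were among the 4.

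The lists past the threshold fell from 2 to 0 in testis and from 1 to 0 in spleen with an estimated correlation and with fry, and from 3 to 0 in brain with an estimated correlation and to 1 with brightness as a covariate. Without single arrays they ranged from 0 to 2 in testis, 1 to 10 in spleen and 2 to 4 in brain. The interaction count of testis and spleen was 2 in the deposited normalized values, 0 for probes detected on all arrays, which left Bclaf3 out, and 1 to 2 without single arrays. That of testis and brain was 0 in both of these settings and 0 to 2 without single arrays, and that of spleen and brain 1 for probes detected on all arrays and 0 to 1 without single arrays. Of the 3 probes lower in heterozygous testes 1 passed in the deposited normalized values. At an unadjusted p under 0.01 the overlap between tissues was 1 instead of 0. Apart from these constructions, the cause was not tested.

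The Smc6 difference turned to 0.0556 in testis with wild-type controls only, and without single arrays ranged from -0.109 to 0.0143 there and from -0.0837 to 0.0211 in brain, where median scaling gave 0.0181. In spleen it ranged from 0.0661 to 0.27 and was 0.0187 without both arrays that carried pancreas transcripts. In spleen Cd4 turned to 0.16 and Bcl11b to 0.0607 without both arrays that carried pancreas transcripts, and Ccna2 to 0.00699 with heterozygous controls only. Without single arrays Bcl11b ranged from -0.28 to 0.11, Fech from -0.0173 to 0.79 and Csf3r from -0.45 to 0.15. The median of the brain heat shock list turned to -0.0184 with brightness as a covariate. The cause was not tested.

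Replicate numbers did not pair the samples: the deviations of controls and mutants with the same number correlated between -0.38 and 0.28, and only some arrays correlated best with their own number. With the number as a block the brain count was 0 in limma, with 1887 probes at an unadjusted p under 0.05, and the testis and spleen counts were 0, with 623 and 162.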

Other observations

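The tests on the Smc6 chromosome and on glucocorticoid-induced genes, and the genes named in this part, were chosen only after the values were seen.

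Several transcripts varied widely between single samples. In brain the pituitary hormone genes Gh, Prl and Pomc ranged from 4.31 to 13.88, 4.32 to 12.26 and 4.30 to 9.59 on the log2 scale and each had high and low values in both controls and mutants. In spleen the sperm protamine gene Prm1 ranged from 5.92 to 10.07 and the transition protein gene Tnp1 from 4.74 to 6.83, and the highest value of both was in mutant replicate 1. The haem synthesis gene Alas2 ranged from 10.55 to 12.92 between spleens. In testis mutant replicate 1 the elastase Cela2a stood at 9.56 and Pnliprp1 at 8.04.

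Erdr1 was higher in mutants in every tissue without passing, with differences of 0.45 in testis, 1.04 in spleen and 1.78 in brain (limma adjusted p = 1.00, 1.00 and 0.131). In brain it ranged from 8.25 to 9.10 in controls and from 9.39 to 11.46 in mutants. Gabra6, a GABA receptor subunit of cerebellar granule cells, differed by 0.59 in brain (SE 0.13, limma adjusted p = 0.130) and Gabrb2, which lies beside it, by 0.39, but of the 10 genes of the cerebellum list 5 lay above 0 and 5 below (camera adjusted p = 0.566). The adult globin gene Hba-a1 read 0.34 in brain (limma adjusted p = 0.243). Of the genes on the X chromosome 17 of 316, or 5.38%, had p under 0.01 in brain, the highest share of a chromosome (Fisher's exact test, p = 0.00639, and 0.134 adjusted over 21 chromosomes).

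A glucocorticoid response in the mutant brains is a hypothesis from Tsc22d3 and Cdkn1a, both of which glucocorticoids induce. A list of other such genes, written before its members were looked up, had a median difference of 0.113 in brain, with 16 of 20 genes above 0 and 6 at an unadjusted p under 0.05, all higher. Sgk1 read 0.52 (SE 0.22), Ddit4 0.32 (SE 0.12) and Tob2 0.25 (SE 0.09), while Fkbp5 and Per1, which answer the same hormone, read -0.06 and -0.03. Camera gave p = 9.51e-05 by its preset correlation, 0.190 with an estimated correlation, and fry 0.189, so the small p rests on the preset correlation and the hypothesis could not be decided. The list's median was 0.03 in testis and -0.12 in spleen.

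Genes on chromosome 12, which holds Smc6 as well as Etv1, Trappc12, Twistnb and Sostdc1, were noticed among those with small p in brain, as alleles linked to a mutated locus in a mixed strain would give. Over the whole chromosome there was no excess: 8 of 332 genes there had p under 0.01, 2.41% against 2.76% elsewhere (Fisher's exact test, p = 0.699), and 24 of 35 splits of the brains gave a Fisher p as small, with 0.0336 in the most extreme other, so chance is not excluded. Linked alleles may span only part of a chromosome, which a test over all of it can miss. Of the 8 genes, Trappc12, Twistnb, Sostdc1 and Etv1 lay at places 53, 68, 73 and 74 in chromosome order. The others lay at 166, 215, 286 and 331. Closeness was tested only through the scan given below, whose best window lay elsewhere. The Smc6 neighbours on chromosome 12 passed fry for change in either direction (adjusted p = 0.0316, but 0.611 in camera). Fry does not compare a list with other genes. Of these 24 genes 1 had an unadjusted p under 0.05, where 1660 of 14027 brain probes did, so that pass does not speak for the locus. The list's differences spanned -0.23 to 0.28, so Trappc12, Twistnb, Sostdc1 and Etv1 were not among its members. Other brain values go with linked alleles: Eipr1, beside Trappc12, read 0.42 to 0.58 on 4 probes and 0.14 on the brightest, the only one counted, and Adi1, on its other side, read -0.43 and -0.66. Trappc12 and Adi1 each had the same 4 lowest animals in testis and spleen, as 1.47% of probes did against 1.43% by chance, while no Eipr1 probe did. These were controls 1 and 4 with mutants 1 and 3 for Trappc12, and with mutants 3 and 4 for Adi1. They do not follow the Smc6 genotype. A scan of 30 neighbouring genes found at most 6 at that p, on chromosome 11 around Gabra6, which 2 of 35 splits reached, with 8 in the highest other. For the 4 genes of chromosome 12 also measured in testis and spleen, deviations from the group means were correlated between both tissues over the 8 animals. The median correlation was 0.476 (permutation p = 0.0279), but 0.203 (permutation p = 0.288) without Trappc12, the gene that prompted the test. With the group means removed, this test sees only alleles that vary within a group, not ones that follow the Smc6 genotype. Strain alleles there and other causes therefore cannot be told apart with so few genes.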
